A study of Mus musculus with 2 samples.

How the data were processed

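Splenic T cells of mice that lack the arginine methyltransferase PRMT5 in T cells (Prmt5 CKO, a floxed Prmt5 gene deleted by a CD4-Cre transgene) and of control mice were profiled by droplet single-cell RNA sequencing. The labels name the C57BL/6 strain, a sort of CD3+ cells by flow cytometry and the 10x Genomics 3′ chemistry V3.1. Each group is 1 library. The design text gives 3 mice per group, and cells were not mapped to mice, so each library counted as 1 sample. The genotype field of both samples reads the same, with Cre and the floxed gene, whereas the titles name a CKO and a control sample. Groups were taken from the titles.

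The deposited matrices hold counts, as whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. Per the submitters' processing notes and the file headers, the authors made them with Cell Ranger 3.1.0. The notes also name CASAVA 1.8, Seurat 2.3.4 and the genome build mm10, without saying which step each served. Positions of genes came from GENCODE vM21, which gave a position for 30843 of the 30905 gene identifiers.

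Cells were kept with at least 500 detected genes and under 10% mitochondrial UMIs. Scrublet, run per library in scanpy with an expected doublet rate of 6%, set thresholds of 0.643 and 0.629 and called 0 doublets in either library. A caller that marks no cell among this many has not worked, so doublets remain in the data, and leaving out the cells with the highest 6% of scores was added as an alternative. Counts per cell were scaled to 10000 and log-transformed. Both libraries were clustered together on 2000 variable genes, without T cell receptor, immunoglobulin, mitochondrial and ribosomal genes, using 30 principal components, 15 neighbours and Leiden resolution 1. Clusters 5 and 9, which mixed classes, were clustered again on 15 components at resolution 0.8, and groups of under 60 cells were not divided further. The seed was 1.

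The leading genes of clusters were set beside 20 marker sets, which cover T cell subsets and the NK, B, plasma, myeloid, dendritic, neutrophil, erythroid, platelet and stromal cells that a sort could carry over. Names came from thresholds on single genes. No rule gave the name of NK, plasma, dendritic, neutrophil, erythroid, platelet or stromal cells. The thresholds that turn markers into names were set after the clusters had been seen. They are percentages of a cluster's cells with a UMI. B-like needed Cd79a in 50%, myeloid-like Tyrobp in 50% with Cd3e under 60%, and proliferating-like Mki67 in 50%. Treg-like needed Foxp3 in 40%, interferon-responding-like Ifit3 in 50%, γδ-like Trdc and S100a4 in 60% each, and NKT-like Zbtb16 in 30%. CD8 clusters needed Cd8b1 in 60% with Cd4 under 20%, and were effector-like with Gzma in 40%, memory-like with Ly6c2 in 70% and Il2rb in 45%, and otherwise naive-like. CD4 clusters needed Cd4 in 30% with Cd8b1 under 25%, and were memory-like with Cd44 in 25% and otherwise naive-like. A cluster with Fcer1g in 25% and Cd8b1 under 60%, clusters with Tnfrsf9 and Xcl1 in 20%, and clusters that met no rule stayed unnamed or mixed. The CD4 class leaves out Treg-like cells. B-like and myeloid-like cells were left out of the T cells.

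With 1 library per group no test across replicates exists, so no p-value and no count of changed genes is given. Genotype and library preparation cannot be told apart. UMIs were summed per class and library and given as CPM, a gene's UMIs relative to all UMIs of the sum, with exact Poisson intervals. Ratios of CKO over control carry exact conditional binomial intervals, and shares of cells carry exact Clopper-Pearson intervals, all at 95%. These intervals cover counting error only. An exception is the comparison of 111 genes that differ in naive-like CD4 cells. Its intervals come from 10000 resamples of those genes and show the spread among genes. Shares of cells with a Klrg1 UMI were taken after thinning each cell to 2000 UMIs in 1 random draw, with shallower cells left out, and also without thinning. The draw was repeated 1000 times to give its spread. That repeat was added after a first drawing scheme, which drew each class separately, had given a higher ratio. For a share of 0 the upper limit given is 3 cells of the total, and a zero count of UMIs was given a floor of 3.

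Named genes followed a rule. In the CD8 and CD4 classes they were the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with a mean of at least 20 CPM, at least 100 UMIs and an interval off 0. In naive-like CD8, naive-like CD4, memory-like or effector-like CD8 and Treg-like cells, 6 of each were taken. Receptor segments, mitochondrial, ribosomal, sex-linked, predicted and pseudogene names were left out of the ranking. Prmt5, Klrg1 and up to 4 members per list with the largest ratios were also named.

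There were 22 gene lists. They cover CD8 terminal effector genes, naive and memory precursor genes, virtual and central memory CD8 genes, inhibitory receptors and exhaustion genes, the type I interferon response, p53 targets, the BCL2 family, and arginine methyltransferases with PRMT5 partners. They also cover the Sm core and SMN complex, common gamma chain signalling, immediate early and dissociation stress genes, ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol synthesis, S phase, and G2 and M phase. The last 5 cover class I MHC presentation, T cell receptor signalling, tissue retention, Treg genes and helper subsets. Each list was described by the median log2 ratio of its members at 20 CPM or more. Members are counted as higher or lower by the sign of their ratio, whether or not its interval lay off 0. Its percentile among 10000 random lists of the same size, matched over 20 expression bins, serves as a description of these libraries. Lists share members, such as Ctla4, Il7r, Bax and Bcl2, and several list members also serve as cluster markers. The ribosomal protein list was drawn by a pattern of gene names and also takes in S6 kinase genes such as Rps6kb1.

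The 3′ tags of Prmt5 fall at the transcript end, in exon 17 of transcript Prmt5-201. The labels do not say which exons the deletion removes, so transcripts without those exons may still be counted, and Prmt5 UMIs are no direct measure of the deletion.

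The self-test drew library sums for 4812 genes with 200 changed at random. All 98 genes changed by 1 log2 unit and all 94 changed by 0.5 among those measured came back off 0 with the right sign (100% each). Intervals covered 95.2% of the unchanged genes, and 90.9% of the lists lay between the 2.5 and 97.5 percentiles. The draws were independent Poisson counts at the depth of whole libraries, so a cover near 95% was built in. The self-test does not cover the smaller sums of single classes or genes whose UMIs sit in few cells.

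Groups, classes to compare, marker sets, lists, the named-gene rule and the first set of alternatives were chosen before the data were examined. Those alternatives were a filter of at least 1000 genes and under 5% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2, each library clustered alone, and clustering without the 517 genes that differ over 2-fold between the library totals. They also included gates of at least 2 Cd8a or Cd8b1 UMIs without Cd4, or at least 1 Cd4 UMI without Cd8, thinning to 1000 UMIs or not at all, median-of-ratios scaling and CPM without ribosomal and mitochondrial genes. The last of them were means over cells and minimums of 5 CPM and 20 UMIs. Added after seeing the data were leaving out the highest 6% of doublet scores, leaving out cells with Xist and Y-linked UMIs together, and using cells with only Xist or only Y-linked UMIs. In the alternatives, list percentiles came from 1000 random lists. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.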

Results

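Splenic CD3+ T cells were profiled by single-cell RNA sequencing in 2 libraries, 1 from Prmt5 CKO mice and 1 from control mice. The CKO library held 7896 cell barcodes with 52387620 UMIs, a median of 5966 UMIs per cell. The control library held 7407 barcodes with 48273424 UMIs, a median of 6054 per cell. After the cell filter 7660 CKO and 6712 control cells remained, of which 7566 and 6620 were T cells. The filter removed 2.99% of CKO barcodes (2.62 to 3.39) and 9.38% of control barcodes (8.73 to 10.1). Few cells were named as other than T cells: B-like cells made up 0.940% of kept CKO and 0.998% of kept control cells, and myeloid-like cells 0.287% and 0.373%. The naming rules held no name for NK, plasma, dendritic, neutrophil, erythroid, platelet or stromal cells, so their absence among the names shows nothing. An unnamed cluster of 278 CKO and 139 control cells had the NK markers Fcer1g and Tyrobp among its 10 leading genes. It was counted among the T cells. With 1 library per group there are no replicates, so values are given with exact 95% intervals that cover counting error only, and differences belong to these libraries as well as to the genotypes.

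The first comparison concerned the targeted gene. Prmt5 encodes the methyltransferase that places symmetric dimethyl marks on arginines of Sm splicing proteins and histones. In all T cells it stood at 4.87 CPM (4.28 to 5.51, 250 UMIs) in the CKO library and 15.03 CPM (13.9 to 16.2, 702 UMIs) in the control, 3.09-fold lower (log2 −1.63). The gene (ENSMUSG00000023110) lies on chromosome 14 of mm10 from 54507187 to 54517525, and its 3′ untranslated region, where 3′ tags fall, spans 54507187 to 54507797 in exon 17. Naive-like cells and Treg-like cells carried the lower level. Prmt5 was 3.22 against 12.1 CPM in naive-like CD4 cells, 4.81 against 15.9 in naive-like CD8 cells and 3.57 against 12.2 in Treg-like cells. In memory-like CD8 cells the CKO library held 13.3 CPM from 10 UMIs and the control 18.0 CPM from 79. In effector-like CD8 cells the values were 8.50 CPM (6 UMIs) and 10.3 CPM (2 UMIs), in memory-like CD4 cells 5.2 (3 UMIs) and 13.1 (29 UMIs), and in γδ-like cells 8.63 (10 UMIs) and 12.8 (3 UMIs). NKT-like cells gave 17.4 CPM from 2 UMIs and 14.1 from 12. B-like cells, in which a CD4-Cre transgene is not active, gave 14.2 CPM from 8 UMIs and 23.6 from 10. These B-like cells also held the T cell transcript Lck, at 400 CPM in the CKO library and 156 CPM in the control, against 1085 and 453 in T cells, so they are no clean background. At these counts a difference was not detectable in the memory-like, effector-like, γδ-like, NKT-like or B-like cells one by one.

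**Figure D1:**
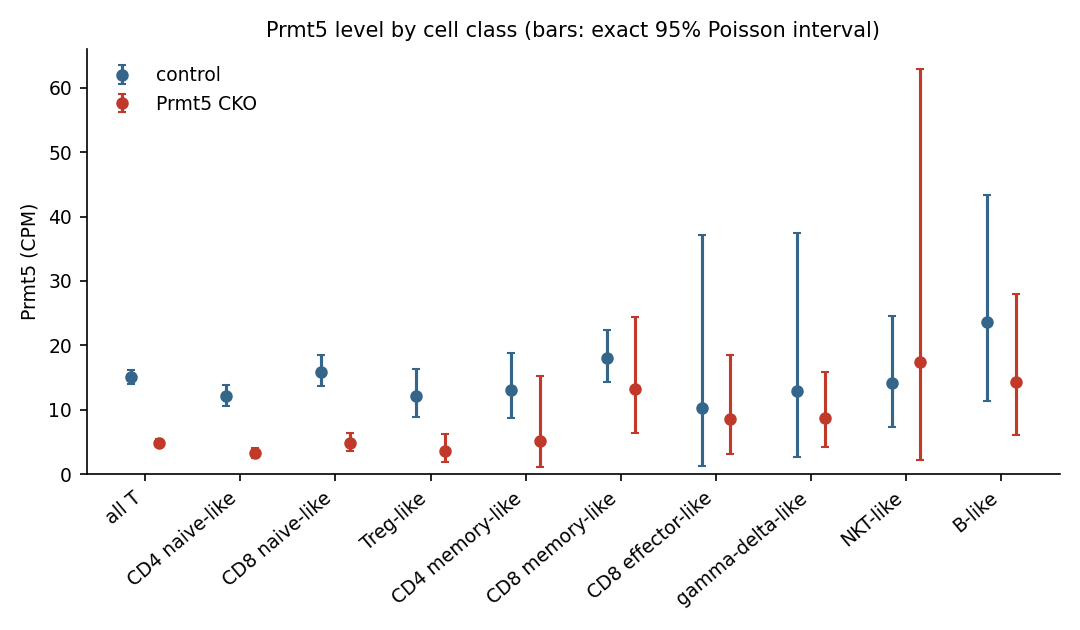
Prmt5 level in CPM by cell class in the CKO and control libraries, with exact Poisson 95% intervals. The CKO values lie at 3.22 to 4.81 CPM in naive-like CD4, naive-like CD8 and Treg-like cells and are higher in memory-like CD8 cells.

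The makeup of the T cells was compared next. CD8 cells, the cytotoxic lineage, made up a smaller part of CKO T cells, and the memory-like cells of both lineages were scarcer within their class. Effector-like CD8 cells, which express granzymes, and γδ-like T cells were more frequent in the CKO library. The sort on CD3 sets which cells could enter these shares. CD8 cells were 20.3% of CKO T cells (19.4 to 21.2, 1534 cells) and 30.2% of control T cells (29.1 to 31.3, 2000 cells). CD4 cells without Treg were 56.7% and 50.5%. Treg-like cells, the Foxp3-expressing suppressor lineage, were 6.24% (5.70 to 6.81) and 7.78% (7.15 to 8.45).

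Within the CD8 class, memory-like cells were 5.74% of the CKO cells (4.63 to 7.02, 88 cells) and 22.2% of the control cells (20.4 to 24.1, 444 cells), 3.87-fold lower. Effector-like cells were 7.43% (6.17 to 8.86, 114 cells) and 1.75% (1.22 to 2.43, 35 cells), 4.25-fold higher (2.89 to 6.39). Naive-like cells were 86.8% and 76.1%. Within the CD4 class, memory-like cells were 1.94% (1.55 to 2.39, 83 cells) and 10.1% (9.11 to 11.2, 338 cells), 5.22-fold lower. Different clusters held this class in the libraries. The cluster led by Maf and Itgb1 held 17 CKO and 247 control cells, that led by S100a4 held 62 and 49, and that led by Tbc1d4 held 4 and 42. Naive-like CD4 cells were also placed unequally, since 1 of their clusters held 1371 CKO and 25 control cells. NKT-like cells, which carry the transcription factor PLZF, were 0.212% of CKO T cells (0.121 to 0.343, 16 cells) and 1.59% of control T cells (1.30 to 1.92, 105 cells), 7.5-fold lower. Cells with γδ-like profiles were 1.90% (1.61 to 2.24, 144 cells) and 0.393% (0.257 to 0.575, 26 cells), 4.85-fold higher (3.18 to 7.67). Interferon-responding-like cells were 5.47% and 3.73%, and proliferating-like cells 1.89% and 1.09%. Among clusters left without a name, the Fcer1g cluster held 3.67% and 2.10% of T cells, the Tnfrsf9 clusters 1.44% and 1.06%, and the mixed clusters 2.22% and 1.56%. Trdc was seen in 49.4% of the cells of the Fcer1g cluster, whose share was 1.75-fold higher in the CKO library. The γδ-like ratio therefore covers only the cluster that met the rule on Trdc and S100a4, and not all cells with Trdc. The proliferating-like cells had a median of 17130 UMIs, 1 mixed cluster 12330 and the larger Tnfrsf9 cluster 11790, so doublets are not excluded there.

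The memory-like and effector-like ratios depended on the cell filter and on the clustering. Without the genes that differ over 2-fold, the ratio of the memory-like CD8 share was 0.708 against 0.258, that of the memory-like CD4 share was 0.340 against 0.191, and that of the Treg-like share was 0.999 against 0.802. With at least 1000 genes and under 5% mitochondrial UMIs, which left 5644 CKO and 3068 control T cells, the effector-like ratio was 2.14 and the memory-like CD4 ratio 0.370. Leaving out the highest 6% of doublet scores gave 0.390 for the memory-like CD8 share, 0.361 for the memory-like CD4 share and 0.999 for Treg-like cells. Cells with Y-linked UMIs alone gave 0.102 for memory-like CD4, 0.0807 for NKT-like and 7.35 for γδ-like cells, and Leiden resolution 0.5 gave 0.309 for memory-like CD4 cells.

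**Figure D2:**
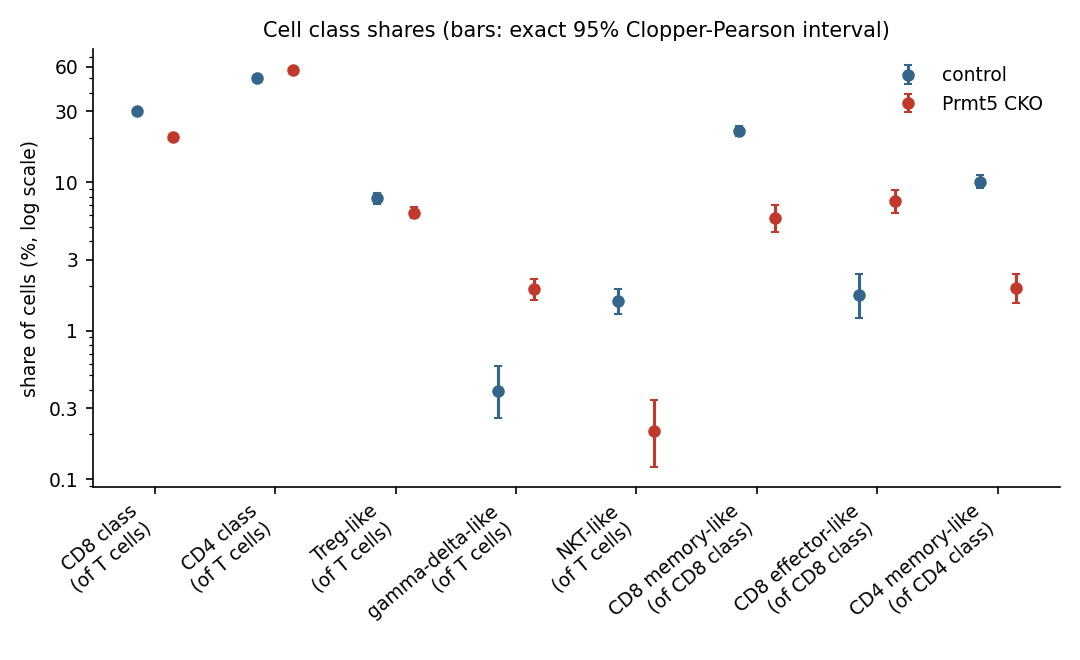
Share of cells, in percent of T cells or of the CD8 or CD4 class on a log axis, in the CKO and control libraries, with exact Clopper-Pearson 95% intervals. Memory-like and NKT-like cells are scarcer in the CKO library, and effector-like CD8 and γδ-like cells are more frequent there.

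The series title points to CD8 cells with Klrg1, a receptor found on short-lived terminal effector cells. The gene (ENSMUSG00000030114) lies on chromosome 6 from 122270596 to 122282882. In the CD8 class it stood at 12.02 CPM (10.1 to 14.2, 135 UMIs) in the CKO library and 2.92 CPM (2.13 to 3.89, 46 UMIs) in the control, 4.12-fold higher (log2 2.04, 1.55 to 2.56). After thinning each cell to 2000 UMIs, 29 of 1530 CKO cells (1.90%, 1.27 to 2.71) and 12 of 1999 control cells (0.600%, 0.311 to 1.05) held a Klrg1 UMI, a ratio of 3.16 (1.56 to 6.79). That is 1 draw. Over 1000 draws the mean shares were 2.27% and 0.553%, a ratio of 4.10, and 95% of the draws gave ratios from 2.81 to 6.53. Without thinning the shares were 4.04% (62 of 1534 cells) and 0.95% (19 of 2000 cells). Thinning left out 4 CKO cells and 1 control cell, and the median depths were 6862 and 7364 UMIs.

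Nearly all Klrg1-positive CD8 cells lay in the effector-like cluster, which was named by Gzma and has Klrg1 in its marker set. Of its cells in both libraries 74.5% held Cd8b1 and 31.5% held Trdc, against 6.41% with Trdc in naive-like CD8 cells. The NK marker Klre1 was among its 10 leading genes, so this cluster may not hold CD8 cells alone. There 27 of 114 CKO cells and 12 of 35 control cells were positive after thinning, 58 and 17 without it. Within that cluster the shares (23.7% and 34.3% thinned, 50.9% and 48.6% unthinned) gave no common order between the libraries. In naive-like CD8 cells 2 of 1328 CKO cells and 0 of 1520 control cells were positive, the latter allowing up to 0.197%. As a background, B-like cells held 1 positive of 72 CKO cells (1.39%, median depth 5633) and 0 of 65 control cells (up to 4.62%, median depth 4495), too few to set a close limit. Naive-like CD4 cells, a larger background, held 2 of 4167 (0.0480%, median depth 5568) and 0 of 2992 (up to 0.1003%, median depth 5726). Klrg1 was also higher in the memory-like CD4 cells of the CKO library, with 10 of 82 cells (12.2%) against 3 of 337 (0.890%) after thinning and 14.5% against 0.888% without it. Those positive cells lay in the cluster led by S100a4, which held 62 of the 83 CKO and 49 of the 338 control cells of that class. The ratio of the CD8 share was 1.92 under the stricter cell filter, with an interval of 0.869 to 4.64 that includes 1, and 5.54 after thinning to 1000 UMIs. With gates on Cd8 and Cd4 UMIs it was 2.52 (1.21 to 5.53), from 24 of 1686 CKO and 12 of 2125 control cells. At Leiden resolution 0.5 the effector-like cells left the CD8 class, and Klrg1 was found in 2 of 1456 CKO and 0 of 1871 control cells.

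Gene levels were then compared within the CD8 class as a whole, 11235088 CKO UMIs against 15782163 control UMIs. Genes of cytotoxic effector cells led the higher side. The granule proteases Gzma (log2 2.94, 342 against 44.7 CPM) and Gzmb (2.78, 39.6 against 5.77 CPM) were among them. So were the calcium-binding proteins S100a4 (3.01, 90.3 against 11.2 CPM) and S100a6 (2.54, 177 against 30.4 CPM), the activating receptor Klrk1 (2.32), the galectin Lgals1 (1.52) and the chemokine Ccl5 (1.27, 2703 against 1120 CPM). Lck, the kinase that starts T cell receptor signalling, was higher (1.46, 1257 against 456 CPM). It is ENSMUSG00000000409 on chromosome 4 from 129548344 to 129573641. Usp18, a brake on interferon signalling, was higher by 1.38, and Ggt1, Tesc and Anxa2 by 1.12 to 1.47. On the lower side stood the AP-1 factors Fosl2 (−1.05) and Maff (−0.96), the chemokine receptor Cxcr4 (−0.91, 85.8 against 161 CPM), the costimulatory receptor Cd28 (−0.70, 157 against 255 CPM) and the signalling protein Malt1 (−0.74). Vps37b, Them6, Tpm3-rs7, H2-Ke6, Irs2, Dusp10 and Ifitm10 lay between −0.92 and −0.64.

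The terminal effector list stood out in the CD8 class. Members of a list are counted by the sign of their ratio. Of its 12 measured members 11 were higher, with a median log2 ratio of 1.40, above all 10000 random lists (percentile 100). Gzma also served to name the effector-like cluster. Oxidative phosphorylation genes were higher in 76 of 77, with a median of 0.25 (percentile 100), including the complex I assembly factor Ndufaf4 (0.75), Ndufa7 (0.47) and Cox8a (0.41). The median mitochondrial share of kept cells was 4.33% in the CKO and 5.09% in the control library. Of the 17 interferon response genes 13 were higher, with a median of 0.22 (percentile 98.3), among them Isg15 (0.74) and Ifi47 (0.53). The 4 measured Treg-list genes had a median of 0.39 (percentile 99.7), with Ikzf2, which encodes Helios, at 0.89 and Ctla4 at −0.56. Genes of the ribosomal protein list, which also holds the kinase gene Rps6kb1 (0.30), were lower in 70 of 90, with a median of −0.085 (percentile 0.22). Immediate early and dissociation stress genes were lower in 9 of 13 (median −0.11, percentile 0.11), with Junb at −0.43 and Zfp36 at 0.51. Class I MHC presentation genes were lower in 9 of 12 (median −0.12, percentile 0.36), with H2-Q7 at −0.51 and Psmb8 at 0.22. Of 4 inhibitory receptor and exhaustion genes 2 were lower (median −0.15, percentile 1.28), and Cd160 was at 0.78.

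The other lists of the CD8 class lay within the central range of random lists. Naive and memory precursor genes split 7 to 7 (median −0.0028, percentile 8.15), with the survival gene Bcl2 at 0.61, Il7r at 0.43 and the lymph node homing receptor Ccr7 at −0.58. Virtual memory genes split 3 to 3 (0.038, percentile 21.0), with Ly6c2 at −0.58 and Il2rb at −0.46. Of 9 p53 targets 7 were higher (median 0.16, percentile 81.2), among them the death genes Fas (0.88) and Bax (0.87) and Ccng1 (0.56). The BCL2 family median was 0.071 (5 of 8 higher, percentile 35.5), that of methyltransferases and PRMT5 partners 0.12 (3 of 4 higher, percentile 55.5, with Prmt3 at −0.53) and that of the Sm core and SMN complex 0.11 (11 of 12 higher, percentile 56.6). Common gamma chain signalling stood at 0.13 (7 of 12 higher, percentile 78.4), T cell receptor signalling at 0.055 (13 of 20, percentile 50.2) and tissue retention at 0.16 (8 of 10, percentile 84.6, with Itga4 at 0.50, made up of opposite values in the sets below). Glycolysis stood at 0.072 (8 of 11, percentile 35.1), cholesterol synthesis at 0.10 (2 of 3, percentile 56.1), S phase at 0.22 (7 of 8, percentile 93.7, with Rpa2 at 0.71) and G2 and M phase at 0.21 (3 of 4, percentile 85.6, with Cks2 at 0.60). Helper subset genes were lower in 3 of 3 (−0.12, percentile 5.98), of which Icos, at −0.51, had an interval off 0. The median of all measured CD8 genes was 0.093. At Leiden resolution 0.5, which moves the effector-like cells out of the CD8 class, the terminal effector median relative to random lists was −0.029 against 1.31, and Gzma stood at 0.062, Klrk1 at 0.047 and Ccl5 at 0.066. Under the stricter cell filter Gzma stood at 1.48 and S100a4 at 2.09, and the interferon list relative to random lists was −0.0043 against 0.12.

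**Figure D3:**
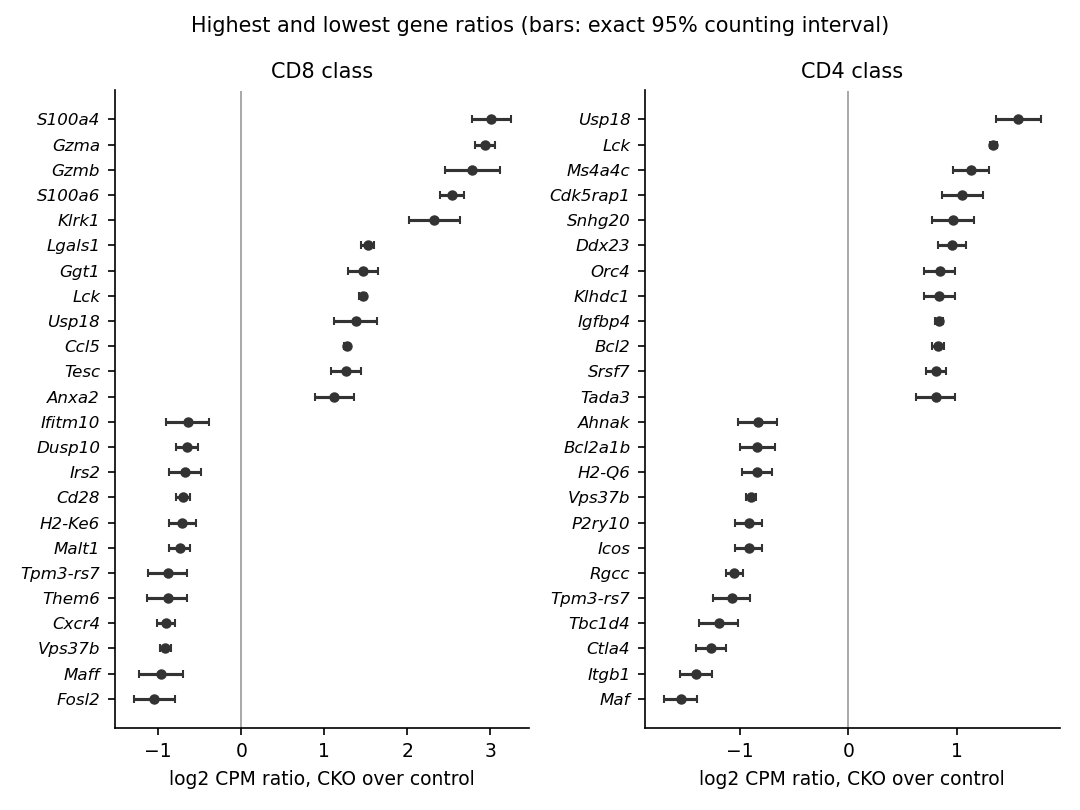
Log2 ratio of CKO over control for the 12 highest and 12 lowest named genes of the CD8 class and of the CD4 class, with counting intervals. S100a4, Gzma and Gzmb lead the CD8 class at 3.01, 2.94 and 2.78, and Maf is lowest in the CD4 class at −1.55.

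Within naive-like CD8 cells, which hold no effector-like cells, Lck (1.53, 1324 against 457 CPM), Usp18 (1.52), the TNF family ligand Tnfsf8 (1.43), Ggt1 (1.32), Lgals1 (1.19) and Ccl5 (1.55, 201 against 68.5 CPM) were highest. Fosl2 (−1.11), Them6 (−1.05), Tpm3-rs7 (−0.99), Vps37b (−0.95), the class I gene H2-Q7 (−0.84, 360 against 644 CPM) and the chemokine receptor Cxcr6 (−0.83) were lowest. The p53 target and BCL2 family lists stood above most random lists here. Of 9 p53 targets 8 were higher (median 0.33, percentile 99.9), and the 7 measured BCL2 family genes were higher (median 0.33, percentile 99.7), 4 of them with an interval off 0. These lists both hold Bax (0.88), Bbc3 and Pmaip1, and their medians were the same value (0.3284), so they are not separate results. The survival gene Bcl2 stood at 0.88. Oxidative phosphorylation was higher in 73 of 77 (0.24, percentile 100) and the interferon response in 10 of 17 (0.20, percentile 99.1). Class I MHC presentation was lower in 9 of 12 (−0.19, percentile 0.02) and tissue retention in 6 of 9 (−0.22, percentile 0.01). The terminal effector list was unremarkable (5 of 6 higher, 0.14, percentile 77.4), as was T cell receptor signalling (10 of 20 higher, median 0.0056, percentile 25.2). Ccl5 stood at 0.16 when clustered without the genes that differ and at 0.066 at Leiden resolution 0.5, and the interferon list relative to random lists was −0.013 under the stricter filter against 0.13. The tissue retention list relative to random lists was −0.10 at Leiden resolution 0.5 and −0.099 when clustered without the genes that differ, against −0.28.

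Memory-like and effector-like CD8 cells as 1 set differed most, and their makeup differed as well, with 114 effector-like and 88 memory-like cells in the CKO library against 35 and 444 in the control. The interferon-induced membrane gene Ifitm1 had 298 UMIs against 0, of which 293 came from 6 effector-like cells. Lgals3 (4.77), S100a4 (4.36), Gzma (4.16), Gzmb (3.97) and S100a6 (3.77) followed. Il6ra (−2.16), Dusp10 (−1.88), Ccr7 (−1.85), Irs2 (−1.76), Treml2 (−1.58) and the methyltransferase Prmt3 (−1.36) were lower. All 21 measured terminal effector genes were higher (median 2.73, percentile 100), and 13 of 14 naive and memory precursor genes were lower (−0.50, percentile 0). Class I MHC presentation, lower in naive-like cells, was higher here in 11 of 12, 8 with an interval off 0 (0.33, percentile 91.3). H2-Q7 stood at 0.72 in the set but at −0.034 (−0.180 to 0.109) in memory-like and −0.057 (−0.235 to 0.123) in effector-like CD8 cells taken alone. Tissue retention was higher in 5 of 8 (0.92, percentile 100). The interferon response was higher in 16 of 16 (0.59, percentile 99.99), and ribosomal proteins were lower in 84 of 90 (−0.34, percentile 0). The median of all measured genes in this set was 0.19. Under the stricter filter no memory-like CD8 cluster formed, so the set held 113 CKO and 35 control effector-like cells alone and is unlike the mixed set. There Gzma stood at 0.25 and Lgals3 at 2.15. Ifitm1 had 0 UMIs in the control effector-like cells of the main setting, so its 4.66 is a lower bound set by the floor of 3 UMIs. Il6ra was 1.21 (−0.508 to 3.58), H2-Q7 −0.16 (−0.325 to 0.0054) and Irs2 −0.047, the terminal effector median relative to random lists was 0.019 against 2.55, that of tissue retention 0.021 against 0.70, that of the interferon response 0 against 0.38, that of ribosomal proteins −0.012 against −0.33 and that of naive and memory precursor genes −0.16 against −0.73. When clustered without the genes that differ, Gzma stood at 2.45 and the terminal effector median at 1.23.

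In the CD4 class without Treg, 25099447 CKO UMIs were set against 20029779 control UMIs. Several of its lowest genes, Maf, Itgb1, Ctla4, Tbc1d4 and Icos, are among the 10 that lead the memory-like cluster with 17 CKO and 247 control cells. Maf, a transcription factor of follicular helper and other effector T cells, was lowest (−1.55, 19.6 against 57.1 CPM). The integrin chain Itgb1 (−1.40, 22.3 against 58.9 CPM), the inhibitory receptor Ctla4 (−1.26, 26.8 against 64.4 CPM), Tbc1d4 (−1.20) and the costimulator Icos (−0.92) followed. Tpm3-rs7, Rgcc, P2ry10, Vps37b, H2-Q6, Bcl2a1b and Ahnak lay between −1.07 and −0.84. On the higher side stood Usp18 (1.56, 36.5 against 12.3 CPM) and Lck (1.33, 1165 against 462 CPM), as in the CD8 class. Ms4a4c (1.13), Cdk5rap1 (1.05), the RNA helicase Ddx23 (0.96), the splicing factor Srsf7 (0.81), the naive-cell gene Igfbp4 (0.83, 717 against 403 CPM) and Bcl2 (0.83, 375 against 211 CPM) were also higher. Snhg20, Orc4, Klhdc1 and Tada3 lay between 0.80 and 0.97.

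Lists of helper function and homing were lower in the CD4 class. All 4 measured helper subset genes were lower (median −0.64, percentile 0), including Cd40lg (−0.35). Inhibitory receptor and exhaustion genes were lower in 3 of 3 (−0.66, percentile 0), 2 of them, Ctla4 and Nr4a3 (−0.66), with an interval off 0. Tissue retention genes were lower in 5 of 7 (−0.37, percentile 0), with Cxcr4 at −0.56. Class I MHC presentation was lower in 10 of 12 (−0.14, percentile 0.3), with H2-Q7 at −0.63, H2-D1 at −0.27 and Psmb8 at 0.26. Immediate early and dissociation stress genes were lower in 9 of 13 (−0.12, percentile 0.25), with Hsp90aa1 at −0.30, Jund at −0.29 and Fos at 0.57. Cholesterol synthesis was lower in 3 of 3 (−0.24, percentile 1.53), 2 of them with an interval off 0. Oxidative phosphorylation was higher in 73 of 78 (0.15, percentile 100), with Ndufaf4 at 0.76. The BCL2 family was higher in 4 of 6 (0.34, percentile 100), and common gamma chain signalling in 9 of 11 (0.13, percentile 98.2), with Socs3 at 0.58. The 4 measured virtual memory genes were higher (0.41, percentile 99.97), 3 of them with an interval off 0, with Il18r1 at 0.64 and Ly6c1 at 0.48.

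The rest of the CD4 lists lay within the central range. Naive and memory precursor genes stood at −0.017 (6 of 14 higher, percentile 17.1), with Il7r at 0.59 and Ccr7 at −0.41, and p53 targets at 0.090 (6 of 10, percentile 87.8), with Bax at 0.58 and Bbc3 at 0.38. The interferon response stood at −0.042 (8 of 17 higher, percentile 8.27), with Irgm1 at −0.52, and T cell receptor signalling at −0.035 (7 of 20, percentile 6.67), with Nfatc1 at −0.56 and Cd28 at −0.51. Terminal effector genes stood at 0.074 (5 of 7, percentile 73.2), the methyltransferase list at 0.083 (3 of 4, percentile 73.7), the Sm core and SMN complex at 0.098 (9 of 12, percentile 90.8) and ribosomal proteins at 0.016 (53 of 89, percentile 71.6). Glycolysis stood at −0.020 (5 of 10, percentile 21.4), S phase at 0.046 (5 of 7, percentile 61.2), G2 and M phase at −0.052 (2 of 4, percentile 19.3) and the Treg list at −0.025 (2 of 4, percentile 30.8). The virtual memory median relative to random lists was −0.11 with members down to 5 CPM and −0.094 under the stricter filter, against 0.38. With gates on Cd4 and Cd8 UMIs the G2 and M phase median relative to random lists was −0.69 against −0.097.

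**Figure D4:**
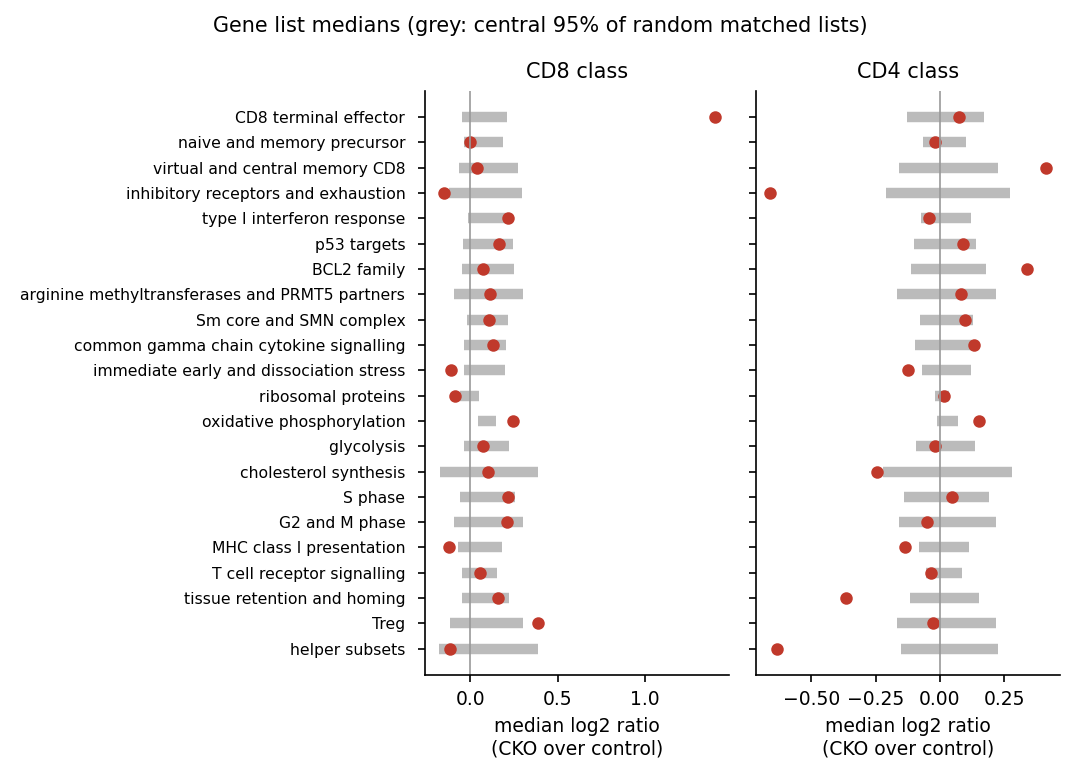
Median log2 ratio of CKO over control for each of the 22 gene lists in the CD8 and CD4 classes (points), with the central 95% of random lists matched on expression in grey. The terminal effector list lies far above random lists in the CD8 class, and the helper, inhibitory and exhaustion, and tissue retention lists lie below them in the CD4 class.

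Naive-like CD4 cells, without the memory-like cells, held part of these differences. Their lists have fewer measured members than those of the whole class, and the 2 sets were not compared by a test. Usp18 (1.68), Lck (1.41), Tnfsf8 (1.26), Ms4a4c (1.21), the splicing factor Prpf3 (1.17) and Cdk5rap1 (1.07) were highest. Rgcc (−1.14), Tpm3-rs7 (−1.07), Vps37b (−0.96), P2ry10 (−0.90), the phosphatase Dusp10 (−0.87) and Fam173a (−0.79) were lowest. Oxidative phosphorylation was higher in 75 of 78 (0.18, percentile 100) and the BCL2 family in 4 of 5 (0.29, percentile 99.6). Of 10 p53 targets 6 were higher (0.12, percentile 90.4). Helper genes (3 of 3 lower, 2 with an interval off 0, −0.31, percentile 0.185) and tissue retention genes (4 of 6 lower, −0.13, percentile 0.85) were lower. Inhibitory receptor and exhaustion genes (3 of 3 lower, 2 with an interval off 0, −0.59, percentile 0) and class I MHC presentation (10 of 12 lower, −0.091, percentile 0.940) were also lower. Naive and memory precursor genes were lower in 8 of 14 (−0.096, percentile 0.27), and terminal effector genes were higher in 4 of 4, 2 with an interval off 0 (0.39, percentile 99.94). Relative to random lists the terminal effector median was 0.024 when clustered without the genes that differ, 0.014 without the highest doublet scores and lower still at Leiden resolution 2, against 0.35. T cell receptor signalling split 10 to 10 (median 0.00076, percentile 28.1).

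Treg-like cells, with 472 CKO and 515 control cells, were compared last. They came from 2 clusters, 1 with 353 CKO and 312 control cells and 1, in which Klrg1, S100a4, Ctla4 and Maf are among the leading genes, with 119 and 203. Ifitm3 (2.51, 55.3 against 9.71 CPM), Plac8 (2.18), Ctla2a (2.07), the galectin Lgals3 (1.66), Sorcs2 (1.63) and the histone gene Hist1h2bc (1.58) were higher. The transcription factor Nfil3 (−1.74), Nt5e, which encodes the adenosine-producing enzyme CD73 (−1.57, 32.7 against 97.1 CPM), Gem (−1.50), the cytokine Tnfsf11 (−1.45), Eea1 (−1.38) and Matk (−1.26) were lower. Klrg1 stood at 138 CPM (125 to 151) against 56.0 CPM (48.6 to 64.3), log2 1.30. After thinning, 59 of 468 CKO cells (12.6%) and 21 of 507 control cells (4.14%) held it, with 4 and 8 cells left out, and without thinning 16.5% and 7.57%. The median depths were 5773 and 5852 UMIs. The 9 measured terminal effector genes were higher (0.91, percentile 100), 8 of them with an interval off 0, and 5 of 6 inhibitory receptor and exhaustion genes were lower (−0.53, percentile 0), 4 with an interval off 0, with Ctla4 at −0.78. T cell receptor signalling was lower in 16 of 20 (−0.12, percentile 0.25), although Lck stood at 1.09. Oxidative phosphorylation was higher in 71 of 78 (0.20, percentile 100). Of 13 Treg-list genes 9 were higher (0.11, percentile 86.6). Fas stood at 0.996, Maf at −0.86 and Icos at −0.74. Klrg1 in Treg-like cells was −0.52 under the stricter filter (−3.42 to 2.38) and −0.022 when clustered without the genes that differ (−1.68 to 1.67), which give no direction, as did Ctla2a at −0.20 (−1.69 to 1.35) under that filter. Lgals3 had 0 control UMIs under that filter and without the highest doublet scores, where the floor of 3 UMIs gives lower bounds of −1.11 and −0.19 and no direction. Klrg1 stood at 0.64 with gates and 0.55 without the highest doublet scores. The terminal effector median relative to random lists was 0.27 under the stricter filter and 0.23 without the genes that differ, against 0.89, and Matk stood between −2.77 in cells with Y-linked UMIs alone and −0.58 in cells with Xist alone.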

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

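No test was run on the values in this part, and the genes in it were picked after the CD8 and CD4 ratios had been seen. The log2 ratios of 7 genes had intervals off 0 on opposite sides in the CD8 and CD4 classes, and the difference between the classes was not tested. S100a6 stood at 2.54 in the CD8 class and −0.66 in the CD4 class, and Anxa2 at 1.12 and −0.59. Ikzf2 stood at 0.89 and −0.47, Ahnak at 0.54 and −0.84, Itga4 at 0.50 and −0.36, and Itgb1 at 0.27 and −1.40. Ms4a4c went the other way, at −0.19 in the CD8 class and 1.13 in the CD4 class. For 3 of the genes the opposite signs depended on the processing. S100a6 in the CD4 class was 0.061 to 0.42 under 5 alternatives, Itgb1 in the CD8 class was −0.62 at Leiden resolution 0.5, and Ms4a4c there was 0.11 under the stricter filter (−0.108 to 0.329).

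Among barcodes outside the compared cells, the filter removed 9.38% in the control library and 2.99% in the CKO library. High mitochondrial content accounted for 673 control and 212 CKO barcodes, and few genes for 389 and 127, with overlap. Among cells that could be scored for sex by Xist or Y-linked UMIs, 5.01% of CKO cells (4.46 to 5.60) and 3.48% of control cells (3.00 to 4.03) held both kinds. Those cells had median depths of 11820 and 11380 UMIs, against 6224 and 6479 in cells with a single kind.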

How the results depend on the processing

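The tests of this part were chosen before the data were examined, except those on doublet scores and on sex-scored cells, which were chosen afterwards. With 1 library per group there were no pairs of samples to analyse. Of 88 recomputed ratios of shares, Klrg1 and Prmt5, 72 stayed within the main counting interval, 16 moved outside it and none changed direction. The Prmt5 ratio stayed between 0.288 and 0.338, and the Klrg1 ratio between 1.92 and 5.54. Of 2296 gene values 1814 stayed, 468 moved and 14 reversed. Of 1063 list values 972 stayed, 86 moved and 5 reversed. The number of named genes that the rule would name again stayed within 1.5 times in 68 of 86 cases, and 77 of 80 medians of all genes stayed. Part of the unchanged values was fixed in advance. Keeping doublets repeated the main setting. Median-of-ratios scaling and CPM without ribosomal and mitochondrial genes shift nearly all genes alike. They could therefore hardly move list values, taken relative to random lists, or the choice of named genes. The causes of the shifts that follow were not tested.

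Under the stricter cell filter, which left 5644 CKO and 3068 control T cells, the ratio of the CD8 share was 0.820, of effector-like CD8 cells 2.14 and of memory-like CD4 cells 0.370. Leiden resolution 0.5 gave 0.309 for memory-like CD4 cells, and resolution 2 gave 0.192 for memory-like CD8 cells. Clustering without the genes that differ gave 0.999 for Treg-like cells, 0.708 for memory-like CD8 cells and 0.340 for memory-like CD4 cells. Without the highest doublet scores these were 0.999, 0.390 and 0.361. Cells with Xist alone gave 0.931 for Treg-like cells. Cells with Y-linked UMIs alone gave 0.749 for the CD8 share, 0.643 for Treg-like, 0.181 for memory-like CD8 and 0.102 for memory-like CD4 cells. Keeping doublets moved nothing, since none had been called.

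Of the reversed values, S100a6 in the CD4 class was 0.19 under the stricter filter, 0.061 at resolution 0.5, 0.39 without the genes that differ, 0.16 with gates and 0.42 without the highest doublet scores, against −0.66. Klrg1 in Treg-like cells was −0.52 under the stricter filter and −0.022 without the genes that differ, against 1.30, with wide intervals over 0. Itgb1 in the CD8 class was −0.62 at resolution 0.5 (main 0.27), and Ms4a4c there was 0.11 under the stricter filter (main −0.19). That filter left only effector-like cells in the set of memory-like or effector-like CD8 cells, where H2-Q7 was −0.16 (main 0.72) and Il6ra 1.21 (main −2.16). In Treg-like cells it gave −0.20 for Ctla2a (main 2.07) and a lower bound of −1.11 for Lgals3 (main 1.66), which had 0 control UMIs there and without the highest doublet scores (−0.19). For lists, relative to random lists, the terminal effector median in the CD8 class was −0.029 at resolution 0.5 (main 1.31). The interferon median under the stricter filter was −0.0043 in the CD8 class (main 0.12) and −0.013 in naive-like CD8 cells (main 0.13). The virtual memory median in the CD4 class was −0.11 with members down to 5 CPM and −0.094 under the stricter filter (main 0.38).

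Some alternatives gave no value. At resolution 0.5 at least 1 library held no memory-like or effector-like CD8 cells, and the Klrg1 share rested on 2 CKO cells. Under the stricter filter at least 1 library held no memory-like CD8 cells and at least 1 no NKT-like cells. With each library clustered alone this held for memory-like CD8, NKT-like and γδ-like cells. A ratio was computed only where both libraries held the class, so these cases are outside the counts of ratios above. Gates define only the CD8, CD4 and Treg classes. Median-of-ratios scaling moved the median of all genes in memory-like or effector-like CD8 cells from 0.19 to 0. In the small classes Prmt5 rests on few UMIs, 2 to 10 in the CKO library.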

Other observations

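Tests chosen after the result was seen were those of the Prmt5 ratio between classes, free RNA, the effector-like cells, the memory-like cells by lineage, the highest neighbour of Lck, the sex and Prmt5 level of the naive-like CD4 cluster, and the summed H2-Q genes; the other tests were chosen before it. The genes and cells in this paragraph were also chosen after their values were seen. Phlda3, a p53 target, was below the level of the named genes but stood apart in naive-like CD4 cells, at 7.01 against 0.505 CPM (172 and 9 UMIs, log2 3.80), in naive-like CD8 cells (10.3 against 0.625 CPM, log2 4.05) and in Treg-like cells (19.6 against 2.22 CPM, log2 3.15). Ifitm1, an interferon-induced membrane protein, was found at 3 or more UMIs in 32 CKO T cells, with 1163 UMIs in all, and in 0 of 6620 control T cells. Of those 32 cells 19 had Xist and 5 Y-linked UMIs only, 46.9% held Gzma and 34.4% held the cycling gene Mki67. As 53.1% held Cd4, 62.5% Cd8b1 and 46.9% Trdc, and 10 lay in the proliferating-like and 6 in mixed clusters, doublets are not excluded among them. In γδ-like cells the cytokine gene Il17a was seen in 43.8% of the 144 CKO cells and 46.2% of the 26 control cells, and the δ chain gene Trdc in 79.9% and 50%. Both libraries held cells with Xist alone (3326 CKO, 3233 control) and with Y-linked UMIs alone (2213 and 1671), so both libraries hold female and male cells.

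A first pattern was that Prmt5 UMIs were kept in memory-like, effector-like and NKT-like CKO cells, at 9.76 CPM (6.04 to 14.9, 21 UMIs) against 3.67 CPM in naive-like CKO cells, resting on memory-like CD8 cells (13.3 CPM, 10 UMIs) more than on memory-like CD4 cells (5.2 CPM, 3 UMIs). Free RNA, which reaches all cells alike, is argued against by the 2.66-fold higher level in these cells (1.59 to 4.24). A candidate explanation is incomplete deletion, but the CKO to control ratio there, divided by that in naive-like cells (2.27, 1.35 to 3.70), restates the pattern and lends it no support. Of 111 genes that differ in naive-like CD4 cells, the median signed ratio in effector-like CD8 cells was −0.034 times that in naive-like CD8 cells (−0.187 to 0.289). This interval and those of the next sentence come from resampling the genes and do not cover counting error. Incomplete deletion would give such a low value. It does not decide the question, since the genes were picked in naive-like cells and the effector-like control sum held 35 cells. In memory-like and NKT-like cells together the median was 0.53 times that in naive-like CD8 cells (0.414 to 0.660), made up of 0.33 times in memory-like CD4 cells (0.214 to 0.518) and 0.77 times in memory-like CD8 cells (0.614 to 0.923). In the latter 101 of the 111 genes kept their direction. The lineage with more Prmt5 UMIs thus lacked the differences less. However, the Prmt5 intervals of the CKO memory-like CD8 (6.36 to 24.4 CPM) and memory-like CD4 cells (1.07 to 15.2 CPM) overlap. No order of the lineages in Prmt5 was therefore shown. In Treg-like cells, with Prmt5 at 3.57 CPM in the CKO library, the median signed log2 ratio was 0.46 (0.413 to 0.542 over resampled genes). In naive-like CD8 cells it was 0.58 (0.550 to 0.663). A smaller median was thus also seen in a class with few Prmt5 UMIs. In γδ-like cells (8.63 CPM) it was 0.23 (0.125 to 0.383). Incomplete deletion stays open.

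A second pattern was a naive-like CD4 cluster with 1371 CKO and 25 control cells, 32.6% of the naive-like CD4 cells of the CKO library. The genes that define it against the other naive-like CD4 cells of that library, and so are no separate result, included Fam46a (log2 1.79), Dapl1 (1.34), Il18r1 (1.28), Usp18 (1.11) and Lck (0.90) on the higher side and Sox4 (−1.49), Myb (−1.36) and H2-Q7 (−1.14) on the lower. Cells of a single animal are argued against by a Y-linked share of 49.3% of its scored cells (46.1 to 52.5). Prmt5 stood at 1.07 times the level of the other cells (0.657 to 1.71), which leaves a different degree of deletion open, since Prmt5 UMIs are no direct measure of it. A library-wide difference in a few genes could not be excluded: clustered without the genes that differ, its cells fell in clusters with 18.4% control cells on a weighted average, and 63.8% of them in a cluster with 2.13%, and no biological explanation was tested beyond these.

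The last pattern was lower H2-Q7 and H2-Q6, class I MHC genes of the Q region, in naive-like CD8 (−0.84 and −0.81) and CD4 cells (−0.59 and −0.58), whereas H2-Q4 (−0.064 and 0.049) and H2-Q10 (0.17 and 0.23) had intervals over 0 in both. The sum of the H2-Q genes was also lower, at −0.34 in CD4 (−0.375 to −0.307) and −0.60 in CD8 cells (−0.648 to −0.559). That argues against a mere shift of counted UMIs among near-identical paralogs of the Q region. Reads not assigned to a single paralog may be missing from the counts, and the sum cannot show them. Outside the Q genes, H2-K1 (−0.23 in CD4 and −0.29 in CD8 cells), H2-D1 (−0.25 and −0.31), H2-T22 (−0.34 and −0.47) and H2-T23 (−0.21 and −0.30) were lower too. A strain segment on chromosome 17 cannot be told apart from the genotype, since the gene ratios from 33 to 38 Mb were at the 58.5 percentile of random runs of genes in CD4 and the 97.2 percentile in CD8 cells, although H2-Q7 was at −0.034 in memory-like CD8 (−0.180 to 0.109), −0.057 in effector-like CD8 (−0.235 to 0.123) and 0.45 in memory-like CD4 cells (0.319 to 0.576), not lower as in naive-like cells. For genes within 5 Mb of Prmt5, the median size of the ratios lay at percentiles of 41.0 and 47.4, which argues against a change in most genes there. A median cannot show a segment from another strain that alters few genes, so such a segment stays open. The largest ratios there were those of Zmym5 (0.66 in CD4 and 0.63 in CD8 cells) and Ttc5 (0.60 and 0.73). In all, 29 genes were higher and 13 lower in CD4 cells, and 29 and 12 in CD8 cells. Around Lck, the 9 measured neighbours within 0.5 Mb were all higher, with median log2 ratios of 0.21 in CD8 and 0.19 in CD4 cells. The sizes of these medians lay within the central range of random runs of genes (percentiles 86.1 and 91.3). The neighbours reached 0.69 at most, below Lck itself (1.53 and 1.41), which argues against a gain of the region as the whole cause of its change. The interval of Lck lay over 0 in effector-like CD8 (0.036, −0.26 to 0.342), memory-like CD4 (0.12, −0.044 to 0.289) and γδ-like cells (0.25, −0.137 to 0.654). In memory-like CD8 and Treg-like cells Lck stood at 1.14 and 1.09.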
